A study of Mus musculus with 6 samples.

How the data were processed

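The data are 6 libraries of alveolar macrophages sorted from mouse lung, 3 wildtype and 3 Sdha-KO. Per the labels' protocols, RNA was extracted with TRIzol and libraries were made with a QuantSeq 3' mRNA kit, which primes on poly(A) tails and reads near the 3' ends of transcripts, so counts do not depend on transcript length. The deposited table holds raw read counts per gene symbol, 1 column per library, with no normalization by the authors that the values show. Per the submitters' processing notes, reads were processed with Bowtie2 and bedtools on the mm10 genome. Versions, the gene annotation, the rule for reads with several matches and the use of strand are not given in the sources used here. No molecular identifiers are mentioned, so reads are not independent molecules.

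The table has 23282 rows, of which 7901 are 0 in all 6 libraries. There are 44 rows that repeat a symbol, and they were kept as separate rows. Some rows of near-identical or overlapping genes hold the same counts, such as Ear3 and Ear12 with 861, 1005 and 1284 counts in wildtype replicates 1 to 3, so reads were counted for more than 1 feature. Tsix, transcribed across Xist on the other strand, held 73.6% to 90.1% of the Xist count in the 5 libraries with Xist counts, so counts of genes with overlapping or antisense partners are uncertain. Among genes named here, exons of Sdhaf1, Sdhaf2, Sdhaf4, Mt2, Ear1, Ifrd1, Cox4i1, Hspd1, Junb, Pkm, Ftl1, Cd74, Top2a, Cdkn1a, Slc7a2, Cfb, Ppp1r15a, Xist and Tsix overlap those of another annotated gene. A bowtie-type aligner that does not splice reads can also lose reads across exon junctions, which 3' reads cross less often. Every pair of libraries differed by far more than counting noise (chi-square per degree of freedom of at least 36.5), so none was treated as a copy of another.

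Total counts were 8239600, 5813531 and 8032959 in wildtype replicates 1 to 3 and 8472907, 5400160 and 7269525 in Sdha-KO replicates 1 to 3. A count of 0 allows up to 3 counts, which is 0.25 to 0.666 CPM depending on the library, for counting error only. In the first 2 principal components, with 57.3% and 26.6% of the variance, Sdha-KO replicate 1 and wildtype replicate 1 stood apart from the other libraries.

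Genotypes were compared on the deposited counts with edgeR 4.0.16 (filterByExpr with its minimum count of 10, TMM factors, robust quasi-likelihood F-test) in R 4.3.3, with genotype as the only term. The Benjamini-Hochberg adjusted p threshold was 0.05 over 9963 tested genes. CPM values are scaled by TMM factors, and the SE of a log2 fold change is its size divided by the square root of its F statistic. The biological coefficient of variation was 1.40 with all libraries and 0.677 without both batch 1 libraries. Gene lists (43, of which 41 had at least 3 tested members) were tested with camera at a preset correlation of 0.01, from limma 3.58.1. Alternatives were camera with an estimated correlation and fry. Library measures were compared by exact permutation. Groups, tests, lists and the rule for named genes were chosen before the data were examined, with an exception for the library measures. Their plan did not hold the shares of Rn45s, Rn4.5s and Lars2 or the permutation within batches. It held the share of mitochondrially encoded genes, which have no row in the table.

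The labels give each replicate number a second time as a batch number, so the numbers pair the samples. As a check, deviations from the group means correlated across genes at 0.155, 0.117 and 0.126 for libraries with the same number and between -0.152 and 0.111 for others. The fit with the replicate number as a block was planned as an alternative, and its value stands beside each result whose call it changes.

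The rule for named genes took 4 kinds. The first was Sdha, the other genes of the succinate dehydrogenase list, Lyz2 and Lyz1. The second was up to 12 genes per direction past the threshold with a mean of at least 10 CPM in the higher group and no overlap between groups, leaving out predicted and antigen receptor genes. The third was, from each called list, up to 4 members past the threshold or else its 2 most abundant members, and from other lists up to 2 past the threshold. The last was the 5 genes with the smallest adjusted p outside the second kind. Other genes are said to be chosen after their values were seen, as were the members named because they passed adjusted over a list alone.

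Other planned settings were RLE factors, library totals alone, no filter, a stricter filter, DESeq2 1.42.0, limma-voom with and without quality weights, stricter thresholds, leaving out each library and leaving out ribosomal protein and haemoglobin genes. Settings added after seeing the data were leaving out both batch 1 libraries (with and without the block), leaving out the rows Rn45s, Rn4.5s and Lars2, summing repeated symbols, DESeq2 and limma-voom with the block, and the block with an estimated correlation. Coordinates are those of GENCODE M21 on mm10, and plots were drawn with matplotlib 3.10.9.

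The comparison was tested on simulated data with the means, library sizes and spread of these libraries, with 200 of 9963 genes changed. It called 0 of 100 genes changed 4-fold and 7 of 100 changed 8-fold, with 1 false call. With a low spread (dispersion 0.02) it called 99 of 100 genes changed 2-fold and 100 of 100 changed 4-fold, with 14 false calls among 213. The list test called a simulated 2-fold rise of the glycolysis list at the low spread and not at the spread of these libraries (adjusted p = 0.845). Each simulation was 1 draw in which genes varied independently, without transcripts missing from single libraries as in batch 1. The measured glycolysis list was called with a smaller median log2 fold change of 0.74 (camera adjusted p = 1.18e-05). The simulation therefore does not show how the list test behaves on the measured counts. In the simulation at the spread of these libraries, most single-gene differences of 4-fold were not detectable.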

Results

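Alveolar macrophages are the resident phagocytes of the lung's air spaces. RNA was measured in alveolar macrophages sorted by flow cytometry as CD45, CD11c, F4/80 and SiglecF positive and CD11b negative cells from mouse lung. Mice were wildtype or carried floxed Sdha alleles with LysM-Cre, which expresses Cre recombinase from the Lyz2 locus in myeloid cells (Sdha-KO). Sdha encodes the flavoprotein subunit of succinate dehydrogenase, the enzyme that oxidises succinate in the tricarboxylic acid (TCA) cycle and forms complex II of the respiratory chain. The series asks how this enzyme bears on the state and metabolism of alveolar macrophages. There were 3 wildtype and 3 Sdha-KO libraries, made with a kit that reads the 3' ends of polyadenylated transcripts. The labels give each replicate number a second time as a batch number, so that each of 3 batches holds 1 library of each genotype. They do not say whether a library came from 1 mouse or from a pool, so p-values measure the spread between these libraries, which may be partly technical.

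Total counts ranged from 5400160 to 8472907 per library. The row of the 45S ribosomal RNA precursor, Rn45s, held 36.3%, 57.6% and 44.7% of the counts in wildtype replicates 1 to 3 and 20.9%, 43.4% and 48.2% in Sdha-KO replicates 1 to 3. The batch 1 libraries stood apart. Genes with at least 1 count numbered 7893 in wildtype replicate 1 and 5438 in Sdha-KO replicate 1, against 11383 to 13050 in the other 4 libraries. Of 3447 genes with at least 100 counts in each of those 4 libraries, 136 had no count in wildtype replicate 1 and 612 had none in Sdha-KO replicate 1. The share of counts from ribosomal protein genes was 2.33% ± 0.553 in wildtype and 3.83% ± 1.12 in Sdha-KO libraries (mean ± SD, n = 3; exact two-sided permutation p = 0.1, the smallest that 3 against 3 can give, and 0.8 after Benjamini-Hochberg adjustment over 8 library measures). None of the other 7 measures, which included total count, genes detected and the Rn45s share, gave an exact p below 0.3 when the batches were not considered. The shares of Rn45s, Rn4.5s and Lars2 and the comparison within batches were not in the plan. Within batches, Sdha-KO libraries were higher in 3 of 3 batches for the shares of ribosomal protein and haemoglobin genes and lower in 3 of 3 for genes detected and the share of the Rn4.5s row (exact two-sided paired permutation p = 0.25 each, the smallest that 3 pairs can give).

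**Figure D1:**
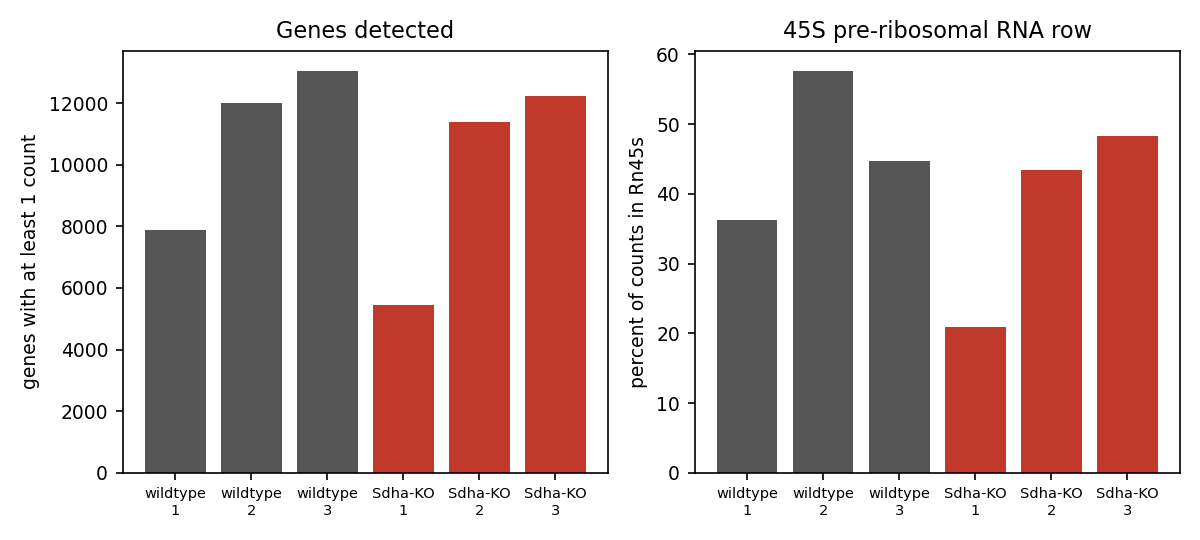
Genes with at least 1 count (left) and the percent of counts in the Rn45s row (right) in each library, with wildtype libraries in grey and Sdha-KO libraries in red. The numbers under the bars are replicate numbers, which are also batch numbers; the 2 batch 1 libraries hold 7893 and 5438 genes, and the other 4 hold 11383 or more.

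The targeted gene was examined first in every library. Sdha (chromosome 13, 74322254 to 74350280, mm10, minus strand) had 457, 295 and 567 counts in wildtype replicates 1 to 3 and 313, 113 and 153 counts in Sdha-KO replicates 1 to 3. Scaled to library size and composition (CPM), this was 64.6 ± 8.13 in wildtype and 23.3 ± 2.59 in Sdha-KO libraries (SD, n = 3). The fitted difference was 2.77-fold lower in Sdha-KO (log2 fold change -1.47, SE 0.818), and all 3 Sdha-KO libraries lay below all 3 wildtype libraries. It did not pass the test across all genes (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p = 1.00). Without both batch 1 libraries, which were left out after seeing the data, the adjusted p was 0.194, and 0.0327 with the replicate number as a block. In the libraries then kept, the mix of sexes also differed between genotypes. Reads from a 3' kit can lie outside the deleted exons, which the sources used here do not name, so this level is a limited check of the deletion. The iron-sulphur subunit Sdhb had 128 ± 71.4 CPM in wildtype and 119 ± 14.8 CPM in Sdha-KO libraries, and Sdhc had 22.1 ± 2.09 and 32.3 ± 20.4 CPM (SD, n = 3 each). Sdhd had no count in either batch 1 library and 16.6, 6.37, 35.1 and 19.5 CPM in wildtype replicates 2 and 3 and Sdha-KO replicates 2 and 3. The assembly factor genes Sdhaf1, Sdhaf2 and Sdhaf4 had log2 differences of 0.80, -0.04 and -0.37 with SEs of 2.32, 1.99 and 2.17 (exons of Sdhaf2 overlap those of Cpsf7, so its count is uncertain), and Sdhaf3 had 5 counts in 1 library and none elsewhere. Lyz2, which carries the Cre insertion, had 0, 23 and 2229 counts in wildtype replicates 1 to 3 and 0, 4 and 38 in Sdha-KO replicates 1 to 3. Its neighbour and close paralog Lyz1 had 0, 60 and 685 counts against 0, 0 and 252. Counts of both genes were lower in Sdha-KO within batches 2 and 3, and were 0 in batch 1. Neither gene passed with 6 libraries, and Lyz2 passed without both batch 1 libraries only with the replicate block (edgeR adjusted p = 0.00126). Without the block its log2 fold change in those libraries was -5.43 (edgeR adjusted p = 0.394). Wildtype replicate 3 held most of the Lyz2 counts, so the size of this difference rests largely on 1 library.

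Sdha-KO macrophages had more RNA of Hilpda, Basp1, Gdf15 and Mt2 and less of Ear1 than wildtype macrophages. Hilpda, which encodes a lipid droplet protein induced by hypoxia, was at 103 ± 12.2 CPM in wildtype and 896 ± 281 CPM in Sdha-KO libraries, an 8.67-fold rise. Basp1, a membrane-associated signalling protein, rose 8.59-fold from 45.8 ± 10.6 to 393 ± 64.4 CPM. Gdf15, a secreted stress-induced cytokine, rose 7.95-fold from 290 ± 36.8 to 2307 ± 1296 CPM. Mt2, a metallothionein that binds zinc and copper, rose 4.88-fold from 251 ± 54.6 to 1226 ± 135 CPM. Ear1, an eosinophil-associated ribonuclease gene expressed by alveolar macrophages, fell 4.78-fold from 633 ± 92.1 to 132 ± 17.7 CPM (SD, n = 3 for each value). In all 5 genes the 3 libraries of 1 genotype lay on 1 side of the 3 of the other.

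These were the only genes of 9963 tested that passed edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. The log2 fold changes were 3.12 for Hilpda (SE 0.351, adjusted p = 0.0117), 3.10 for Basp1 (SE 0.393, adjusted p = 0.0137), 2.99 for Gdf15 (SE 0.386, adjusted p = 0.0137), 2.29 for Mt2 (SE 0.298, adjusted p = 0.0137) and -2.26 for Ear1 (SE 0.321, adjusted p = 0.0261). Hilpda lies on chromosome 6 (29272488 to 29275446), Basp1 on chromosome 15 (25363277 to 25413764), Gdf15 on chromosome 8 (70629393 to 70632456), Mt2 on chromosome 8 (94172664 to 94173568) and Ear1 on chromosome 14 (43818765 to 43875517), all as protein-coding genes of the GENCODE M21 annotation of mm10. Exons of Mt2 overlap a gene on the other strand, and Ear1 shares exonic sequence with a pseudogene and belongs to a family of near-identical copies, so its count is uncertain. With the replicate number as a block, edgeR called 0 genes (296 at an unadjusted p under 0.05, against 263 without the block), and the adjusted p was 0.194 for Hilpda, 0.365 for Basp1, 0.402 for Gdf15, 0.0909 for Mt2 and 0.374 for Ear1; in the same blocked design DESeq2 called 72 genes, all 5 among them, and limma-voom 7, with 1 of the 5 among them. The count was also 0 with a filter asking for 10 counts in all 3 libraries of a group (255 at an unadjusted p under 0.05), 0 without wildtype replicate 1 (340 at an unadjusted p under 0.05), 12 without wildtype replicate 2, 13 without wildtype replicate 3, 3 without Sdha-KO replicate 1 and 2 without Sdha-KO replicate 3. Scaled by library totals alone, 9 genes passed and all 9 were higher, against 4 of 5 with composition factors, and the median log2 fold change of all tested genes moved from -0.13 to 0.05.

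**Figure D2:**
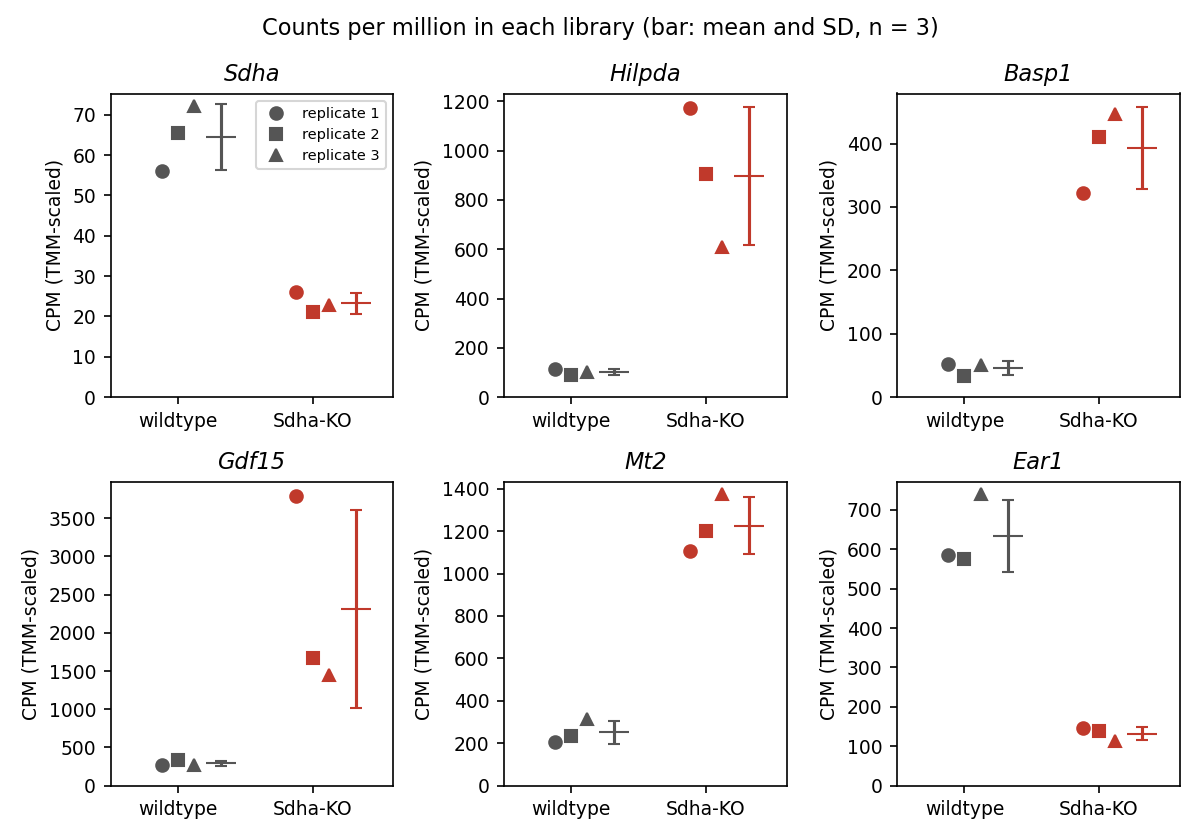
Counts scaled to library size and composition (CPM) of Sdha and of the 5 genes past an adjusted p of 0.05, with 1 point per library, shaped by replicate number, and a bar for the mean and SD of 3 libraries. The linear axes start at 0; the Sdha-KO means of Hilpda, Basp1, Gdf15 and Mt2 are 896, 393, 2307 and 1226 against wildtype means of 103, 45.8, 290 and 251, and Ear1 goes from 633 to 132.

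The next 5 genes in order of adjusted p did not pass the threshold. Ccl9, a chemokine, had 23.9 ± 15.8 CPM in wildtype and 274 ± 64.4 CPM in Sdha-KO libraries (adjusted p = 0.0706). The cysteine protease gene Ctsk had 82.5 ± 15.1 and 437 ± 170 CPM (adjusted p = 0.0706), and Ifrd1 had 279 ± 82.4 and 1038 ± 76.8 CPM (adjusted p = 0.0706), an uncertain count because its exons overlap those of Gm7008. The MHC class II gene H2-Aa had 193 ± 91.7 and 1050 ± 424 CPM (adjusted p = 0.0984), and the glycolytic mutase gene Pgam1 had 20.8 ± 12.6 and 202 ± 24.7 CPM (adjusted p = 0.103; edgeR, SD, n = 3). In all 5 the genotypes did not overlap. Groups did not overlap in 1426 of the 9963 tested genes, 14.3% against the 10% that chance gives for 3 against 3 interchangeable libraries. Sdha-KO was above in 502 and below in 924. These libraries are not interchangeable, as Sdha-KO replicate 1 had no count in 612 of 3447 genes abundant in batches 2 and 3. Such missing counts can put it lowest, so the larger number below is not a measure of genotype alone.

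Because the batch 1 libraries lacked many transcripts, the comparison was repeated without both of them, a choice made after seeing the data. With 2 libraries per genotype 27 genes passed, 15 higher and 12 lower, and these included all 5 genes above. The 22 others, also chosen after their values were seen, included the chemokine gene Ccl3 (4.58-fold higher, adjusted p = 0.0266), the stress-induced phosphatase subunit gene Ppp1r15a (6.28-fold higher, adjusted p = 0.0206; its exons overlap those of Tulp2), Ccl9, Ctsk, Ifrd1, Pgam1, Gpnmb, H2-Aa and H2-Eb1. Among the lower genes were Ear2 (4.98-fold, adjusted p = 0.0155), the complement factor gene Cfb (8.67-fold, adjusted p = 0.0308) and Ctss (2.48-fold, adjusted p = 0.0445; edgeR). Xist and its antisense partner Tsix were also among the lower genes, by 8.27-fold and 8.38-fold. In the libraries kept, the mix of sexes went with genotype. Xist had 4608 and 6055 counts in wildtype replicates 2 and 3 and 498 and 822 in Sdha-KO replicates 2 and 3. The Y-linked gene Ddx3y had 0 and 143 and then 354 and 432 counts. Comparisons without both batch 1 libraries, with or without the block, therefore cannot separate genotype from sex. With the replicate block as well, which leaves 1 residual degree of freedom, 324 genes passed. Among them were genes named here that did not pass in the same 4 libraries without the block: Sdha, Lyz2, Siglecf, Rplp1, Hspa9, Aldoa, Pkm, Fth1, Ftl1, Cd63, Cd74, Ccl6, Junb, Mthfd2, Cdkn1a, Car4, Krt79, Slc7a2, Cd2, S100a6, H2-Ab1 and Psap.

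Gene lists fixed before the data were examined were compared with all other tested genes. Of 41 lists with at least 3 tested members, 14 were shifted by camera with its preset correlation (Benjamini-Hochberg adjusted p under 0.05), 13 up and 1 down. With an estimated correlation only the cytosolic ribosome list passed, and with the replicate block and an estimated correlation no list did. Beside these shifts, the list of immediate early and heat shock genes that tissue dissociation induces was itself shifted up, with 17 of 24 members positive (median log2 fold change 0.54, adjusted p = 0.00015, and adjusted p = 0.315 with an estimated correlation). In that list Junb, whose exons overlap those of Prdx2 and whose count is uncertain, had 469 ± 86.1 CPM in wildtype and 903 ± 231 CPM in Sdha-KO libraries, and Fosb had 545 ± 408 and 886 ± 248 CPM (SD, n = 3). Markers of conventional dendritic cells were positive in 8 of 9 tested members but not called (median 1.46, adjusted p = 0.0944, and adjusted p = 0.696 with an estimated correlation). They were called with the replicate block (adjusted p = 0.0229) and without both batch 1 libraries (adjusted p = 0.000438), and also without a filter on low counts (0.0088) and without wildtype replicate 1 (0.0218), wildtype replicate 3 (0.031), Sdha-KO replicate 1 (0.000866) or Sdha-KO replicate 2 (0.034). Settings that did not call them included leaving out Sdha-KO replicate 3 (camera adjusted p = 0.61), leaving out wildtype replicate 2 (0.114) and the stricter filter (0.584, with 4 members tested).

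**Figure D3:**
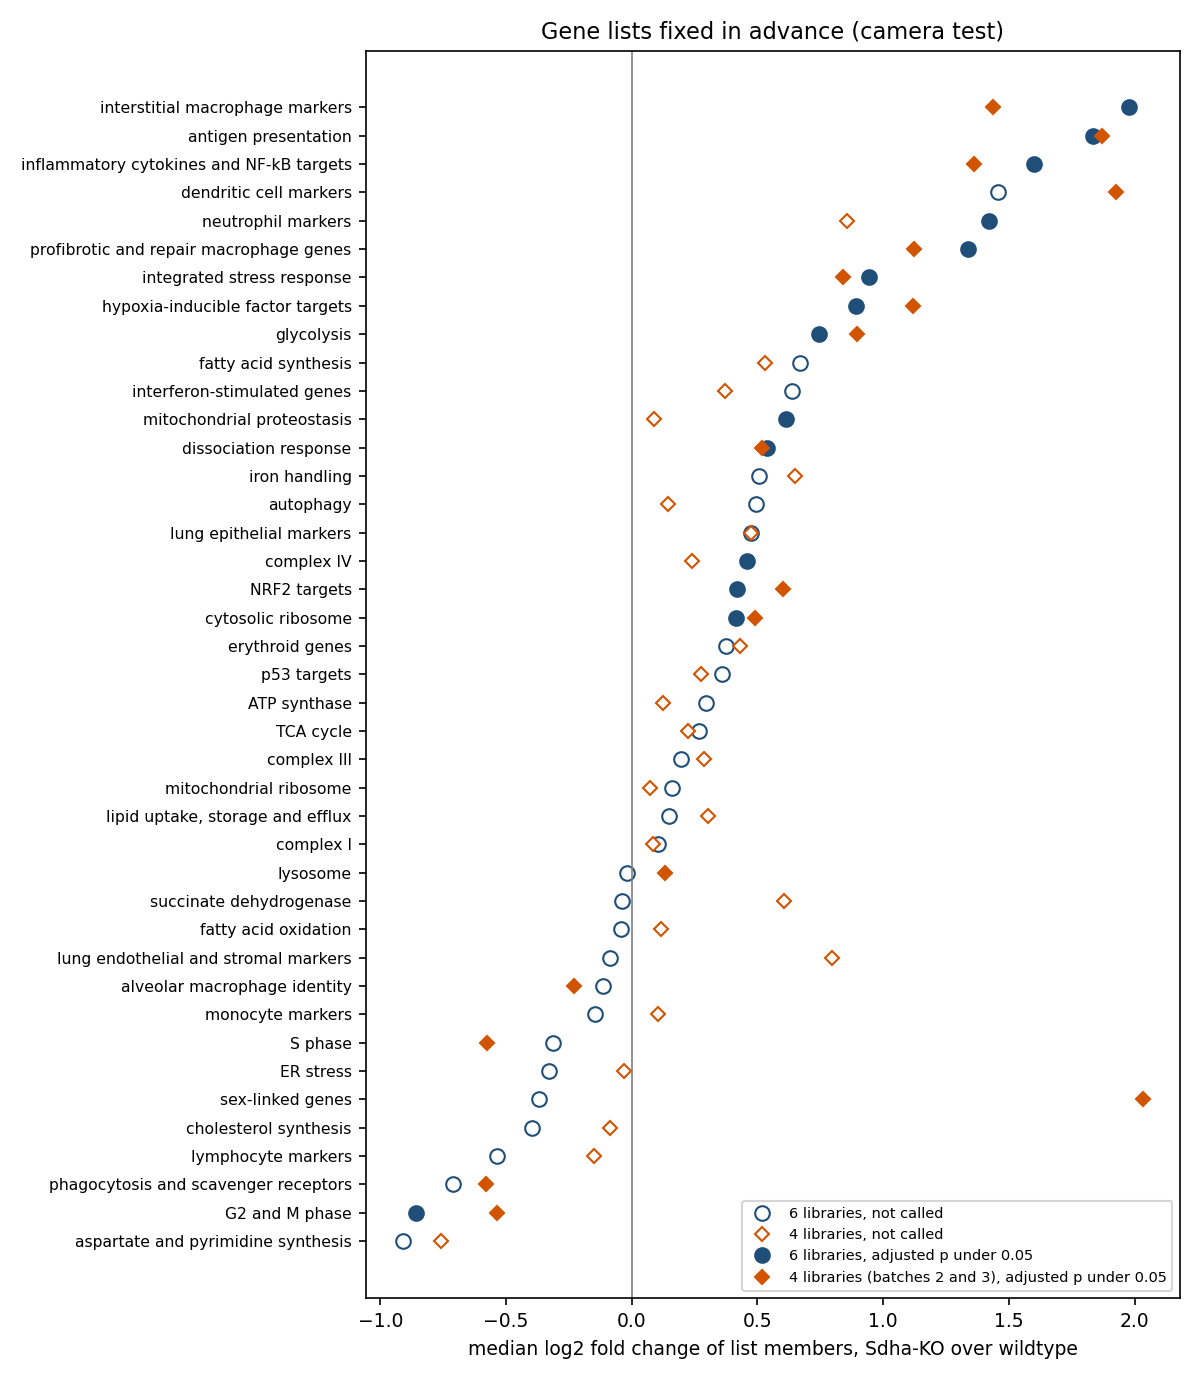
Median log2 fold change (Sdha-KO over wildtype) of the tested members of each of 41 gene lists, from 6 libraries (circles) and from the 4 libraries of batches 2 and 3 (diamonds). Filled symbols mark lists past an adjusted p of 0.05 in camera with a preset correlation, 14 with 6 libraries and 17 with 4; the sex-linked list is called down without batch 1 although its median is 2.03, and is not called with the replicate block as well (adjusted p = 0.233).

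Glycolysis genes were shifted up in Sdha-KO macrophages, with 13 of 19 members positive and a median log2 fold change of 0.74 (camera adjusted p = 1.18e-05, and adjusted p = 0.148 with an estimated correlation). None passed over all genes and 2 passed adjusted over the list alone, Pgam1 and the pyruvate kinase gene Pkm. Pkm had 135 ± 19.2 CPM in wildtype and 448 ± 212 CPM in Sdha-KO libraries, and the aldolase gene Aldoa had 514 ± 155 and 795 ± 173 CPM (SD, n = 3). Targets of hypoxia-inducible factor were shifted up as well, with 17 of 20 positive and a median of 0.89 (adjusted p = 0.000184, and adjusted p = 0.315 with an estimated correlation). The median was 0.39 with the replicate block, 0.45 without Sdha-KO replicate 2 and 0.32 without Sdha-KO replicate 3. Hilpda was the 1 member past the threshold over all genes and the 1 adjusted over the list alone. Targets of the integrated stress response, which the transcription factors ATF4 and CHOP induce, were positive in 27 of 30 (median 0.95, adjusted p = 2.33e-07, and adjusted p = 0.158 with an estimated correlation). Gdf15 passed over all genes, and Gdf15 and the mitochondrial folate enzyme gene Mthfd2 passed adjusted over the list alone. Antioxidant targets of NRF2 were positive in 14 of 20 (median 0.42, adjusted p = 0.0327, and adjusted p = 0.315 with an estimated correlation). The ferritin chain genes of that list had 920 ± 106 and 1969 ± 528 CPM (Ftl1, passing adjusted over the list alone) and 2048 ± 527 and 3342 ± 552 CPM (Fth1, not passing). The NRF2 list was not called without wildtype replicate 2, wildtype replicate 3 or Sdha-KO replicate 1.

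Cytosolic ribosomal protein genes were shifted up, with 74 of 80 positive, a median log2 fold change of 0.41 and no member past the threshold over all genes or adjusted over the list alone. The list passed with the preset correlation (adjusted p = 1.39e-10) and with an estimated correlation (adjusted p = 0.042), but not with the replicate block and an estimated correlation (adjusted p = 0.271). In fry, which asks whether a list's genes move one way and does not compare them with other genes, the adjusted p was 0.02. Rplp1 had 2764 ± 908 and 3941 ± 701 CPM and Rps9 had 1268 ± 136 and 1491 ± 218 CPM in wildtype and Sdha-KO libraries, with overlapping groups for both (SD, n = 3). Of the nuclear genes of the respiratory chain only complex IV was called, with 8 of 11 positive (median 0.46, adjusted p = 0.049, and adjusted p = 0.315 with an estimated correlation). Its highest members, Cox6a1 (179 ± 77.4 and 246 ± 153 CPM) and Cox4i1 (192 ± 32.2 and 203 ± 63.8 CPM), overlapped between genotypes. Counts of Cox4i1, whose exons overlap those of Emc8, and of the chaperone gene Hspd1, whose exons overlap those of Hspe1, are uncertain. Mitochondrial chaperones and proteases were positive in 10 of 15 (median 0.61, adjusted p = 0.0398), with an adjusted p of 0.375 with an estimated correlation and 0.0532 with the replicate block. The median was 0.09 without both batch 1 libraries and -7.22e-05 with the block as well. The chaperone genes Hspa9 (47.4 ± 31.2 and 191 ± 51.6 CPM) and Hspd1 (65.3 ± 30.3 and 161 ± 67.4 CPM) had no overlap between genotypes. Neither list was called without wildtype replicate 2, wildtype replicate 3 or Sdha-KO replicate 1, nor without a filter on low counts (adjusted p = 0.177 for complex IV and 0.0791 for mitochondrial chaperones) or with the stricter filter (adjusted p = 0.0569 and 0.0522). Complex IV was also not called with RLE factors (adjusted p = 0.0531) or without the rows Rn45s, Rn4.5s and Lars2 (adjusted p = 0.0638). Without both batch 1 libraries neither complex IV (adjusted p = 0.192) nor the mitochondrial chaperone list (adjusted p = 0.343) was called. The TCA cycle list other than succinate dehydrogenase (11 of 17 positive, adjusted p = 0.477), complex I (adjusted p = 0.141), complex III (adjusted p = 0.193), ATP synthase (adjusted p = 0.183), the mitochondrial ribosome (adjusted p = 0.477) and succinate dehydrogenase itself (adjusted p = 0.819) were not called. Without wildtype replicate 1, complex I (adjusted p = 0.00447), complex III (adjusted p = 0.0285) and ATP synthase (adjusted p = 0.015) were called up. Complex I was also called without Sdha-KO replicate 2 (adjusted p = 0.034) or 3 (adjusted p = 0.0405), and ATP synthase without Sdha-KO replicate 2 (adjusted p = 0.0472).

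Antigen presentation genes were shifted up, with 9 of 10 members positive and a median log2 fold change of 1.83 (camera adjusted p = 5.48e-05, and adjusted p = 0.315 with an estimated correlation). No member passed over all genes, and 5 passed adjusted over the list alone, 4 up (H2-Aa, H2-Ab1, H2-Eb1 and Cd74) and 1 down (Ctss). Cd74, the invariant chain of MHC class II, had 244 ± 146 CPM in wildtype and 1144 ± 680 CPM in Sdha-KO libraries, and Ctss, the protease that cleaves it, had 3524 ± 413 and 1364 ± 254 CPM (SD, n = 3). Markers of interstitial and recruited macrophages were positive in 16 of 17 (median 1.98, adjusted p = 1.18e-05, and adjusted p = 0.315 with an estimated correlation), with Gpnmb and Cd63 passing adjusted over the list alone. The median was 1.23 without wildtype replicate 1, 0.98 without Sdha-KO replicate 2 and 1.16 without Sdha-KO replicate 3. Gpnmb, a lysosomal glycoprotein gene, had 415 ± 232 and 1048 ± 311 CPM, and the tetraspanin gene Cd63 had 102 ± 54.2 and 401 ± 169 CPM. Profibrotic and repair genes, a list that also holds Gpnmb, were positive in 10 of 13 (median 1.34, adjusted p = 0.000164, and adjusted p = 0.315 with an estimated correlation), and the fatty acid binding protein gene Fabp5 had 187 ± 13.5 and 333 ± 99.8 CPM. Inflammatory cytokines and NF-kB targets were shifted up, with 25 of 27 positive (adjusted p = 1.25e-17, and adjusted p = 0.158 with an estimated correlation). Ccl9 and Ccl3 passed adjusted over that list alone. Ccl6 had 4705 ± 1938 and 9072 ± 2056 CPM, and Nfkbia, the NF-kB inhibitor, had 1030 ± 758 and 3250 ± 964 CPM, with wildtype replicate 3 at 1881 CPM. The dissociation response and dendritic cell lists moved the same way as these groups. Neutrophil markers, with only 5 tested members, were all positive (median 1.42, adjusted p = 0.0398, and adjusted p = 0.315 with an estimated correlation). That list was not called without both batch 1 libraries (adjusted p = 0.192) or without any single library other than wildtype replicate 2. It was also not called without a filter (adjusted p = 0.142), with the stricter filter (adjusted p = 0.0616) or without the rows Rn45s, Rn4.5s and Lars2 (adjusted p = 0.0638), and S100a8 (54.1 ± 32.8 and 67.1 ± 9.14 CPM) and Mmp8 (18.6 ± 3.62 and 49.8 ± 38.8 CPM) overlapped between genotypes.

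Mitosis genes were the 1 list shifted down, with 21 of 24 members negative and a median log2 fold change of -0.86 (camera adjusted p = 0.0327, and adjusted p = 0.696 with an estimated correlation). Top2a, a topoisomerase of dividing cells, had 147 ± 13.7 CPM in wildtype libraries and 0, 89.1 and 102 CPM in Sdha-KO replicates 1 to 3, and the tubulin gene Tubb5 had 456 ± 116 and 343 ± 119 CPM (SD, n = 3). The list was not called without wildtype replicate 2, wildtype replicate 3 or Sdha-KO replicate 1 or with the stricter filter (adjusted p = 0.061), but was without both batch 1 libraries (median -0.53, adjusted p = 0.00392). S phase genes were not called (median -0.31, adjusted p = 0.175) except without both batch 1 libraries (adjusted p = 0.00611), without wildtype replicate 1 and without a filter on low counts.

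Markers of mature alveolar macrophages were not shifted as a list (14 of 34 positive, median -0.11, adjusted p = 0.659), and members moved both ways. Adjusted over the list alone, Ctsk, Slc7a2 and Car4 were higher and Ear1, Ear2, Krt79 and Cd2 were lower in Sdha-KO, while over all genes only Ear1 passed. Other members, chosen after their values were seen, had overlapping groups: Chil3 had 4728 ± 616 and 4311 ± 967 CPM, Lpl had 1016 ± 105 and 1178 ± 265 CPM, and Marco had 307 ± 112 and 361 ± 201 CPM (SD, n = 3). Siglecf, whose protein was used for the sort, had 103, 138 and 132 CPM in wildtype replicates 1 to 3 and 0, 39.6 and 45.3 CPM in Sdha-KO replicates 1 to 3 (edgeR adjusted p = 1.00; without both batch 1 libraries, adjusted p = 0.0942 and 0.0022 with the replicate block as well). The list was called down without both batch 1 libraries (median -0.23, adjusted p = 0.0173) and without Sdha-KO replicate 1 (adjusted p = 0.00663).

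The remaining lists were not called with 6 libraries. Their camera adjusted p-values were 0.062 for autophagy, 0.129 for iron handling, 0.129 for lysosome, 0.219 for phagocytosis and scavenger receptors, 0.242 for interferon-stimulated genes, 0.246 for p53 targets and 0.305 for lipid uptake, storage and efflux. They were 0.305 for cholesterol synthesis, 0.307 for fatty acid synthesis, 0.827 for fatty acid oxidation, 0.455 for targets of the endoplasmic reticulum stress response and 0.477 for aspartate and pyrimidine synthesis. In markers of other cells they were 0.548 for monocytes, 0.974 for lymphocytes, 0.677 for lung epithelium, 0.869 for endothelium and stroma and 0.307 for erythroid genes, and 0.763 for sex-linked genes. Autophagy was called up without Sdha-KO replicate 3 (adjusted p = 0.0491) and lysosome without wildtype replicate 1 (adjusted p = 0.00275), without both batch 1 libraries (adjusted p = 0.0217) and with library totals (adjusted p = 0.0466). Phagocytosis and scavenger receptors were called down without both batch 1 libraries (adjusted p = 0.04), and so were sex-linked genes (adjusted p = 0.0149, and adjusted p = 0.233 with the replicate block as well). Members that passed adjusted over their list alone were Cdkn1a (p53 targets), Ftl1 (iron handling), S100a6 (monocytes) and, among lysosome genes, Ctsk and Psap as higher and Ctss as lower. Test and median differed in sign for the monocyte, lymphocyte, lysosome, succinate dehydrogenase, fatty acid oxidation and sex-linked lists. Eosinophil markers, which were of interest because eosinophils also carry SiglecF, had no tested member, and Epx had no count in any library. No row of the table carried a mitochondrially encoded gene of the fixed list.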

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

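The settings without both batch 1 libraries, without Rn45s, Rn4.5s and Lars2, with summed symbols and with the block in DESeq2, limma-voom or an estimated correlation were chosen after seeing the data. Of 5 genes past the threshold (4 higher, 1 lower), all 5 stayed called with RLE factors, summed symbols, a log2 fold change over 1, and without ribosomal protein or Rn45s, Rn4.5s and Lars2 rows. edgeR called 0 genes (0 higher, 0 lower) with the replicate block, with the stricter filter and at an adjusted p under 0.01. It called 9 (9 higher, 0 lower) on library totals, 48 (35 and 13) without a filter, 27 (15 and 12) without both batch 1 libraries and 324 (178 and 146) with the block as well. DESeq2 called 21 (12 and 9) and 72 (21 and 51) with the block, limma-voom 20 (14 and 6) and 7 (5 and 2) with the block, and limma-voom with quality weights 45 (39 and 6). Leaving out 1 library gave 0 to 13 genes (0 to 12 higher, 0 to 3 lower), with 0 without wildtype replicate 1. The causes were not tested. Over 21 alternatives the log2 fold change was 2.88 to 3.45 for Hilpda, 2.91 to 3.37 for Basp1, 2.38 to 3.41 for Gdf15, 2.16 to 2.54 for Mt2 and -2.41 to -1.96 for Ear1, with adjusted p up to 0.194, 0.365, 0.402, 0.179 and 0.382. All 5 genes kept their sign, and were lost in 4 (Hilpda, Gdf15), 5 (Basp1, Mt2) or 7 (Ear1) of them.

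The 14 called lists became 1 with an estimated correlation, 1 with fry and 0 with the replicate block and an estimated correlation; the other settings gave 10 to 19. Leaving out 1 library gave 10 to 19. With the replicate block 14 lists were called, 13 of them the same. Over all alternatives the median log2 fold change was 0.33 to 0.67 for the cytosolic ribosome, 0.67 to 0.97 for glycolysis, 0.32 to 1.29 for hypoxia-inducible factor targets, 0.70 to 1.10 for the integrated stress response, 0.22 to 0.65 for NRF2 targets, 0.98 to 2.32 for interstitial macrophages, 1.19 to 2.61 for antigen presentation, 1.18 to 2.26 for NF-kB targets, 0.90 to 2.41 for profibrotic genes, 0.31 to 0.97 for dissociation, -7.22e-05 to 0.91 for mitochondrial chaperones, 0.09 to 0.80 for complex IV, 0.55 to 1.57 for neutrophils and -1.75 to -0.45 for mitosis. Leaving out 1 library moved the median by over 1.5 times for mitochondrial chaperones (0.19 without wildtype replicate 1, 0.33 and 0.29 without Sdha-KO replicates 1 and 3), complex IV (0.09 without Sdha-KO replicate 1), NRF2 targets (0.22), antigen presentation (1.19) and mitosis (-1.75) without Sdha-KO replicate 3, mitosis without Sdha-KO replicate 1 (-0.45), dissociation (0.32, 0.97 and 0.31 without wildtype replicates 1 and 3 and Sdha-KO replicate 3), neutrophils (0.89 without wildtype replicate 1) and profibrotic genes (2.41 without wildtype replicate 3), besides hypoxia-inducible factor targets and interstitial macrophages. The sex-linked list, up by camera with 6 libraries (median -0.37), was called down without both batch 1 libraries with a median of 2.03 (adjusted p = 0.0149, and adjusted p = 0.233 with the replicate block as well). Without both batch 1 libraries Xist and Tsix passed as lower. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had positive log2 fold changes there (1.67 to 2.81), but none passed (edgeR adjusted p = 0.507 to 0.937). Results without both batch 1 libraries therefore cannot separate genotype from the mix of sexes. Among single genes 763 comparisons kept their side of the threshold, 88 gained it and 25 lost it; among lists 672 kept it, 28 gained it and 74 lost it. With 6 libraries the replicate block changed no call of a named gene or list other than the 5 genes, the mitochondrial chaperone list and the dendritic cell list. Depth was 5400160 counts or more, of which Rn45s took 20.9% to 57.6%. The batch 1 libraries held 7893 and 5438 genes, so a difference in a gene at 0 in both rests on the other 4 libraries. Where only Sdha-KO replicate 1 is at 0, that 0 enters the fit with 6 libraries. Top2a, with 1328 counts in wildtype replicate 1 and 0 in Sdha-KO replicate 1, had a log2 fold change of -1.21. Without both batch 1 libraries that of Top2a was -0.53.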

Other observations

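The tests of scaling, of sex, of batch and of dendritic cells and the small RNA list were chosen after the result was seen, and the dendritic cell test was replaced 1 time and the sex test 2 times after values were seen, the earlier sex tests having compared libraries that differ in Xist and Y-linked counts. Genes of small non-coding RNAs (nuclear, nucleolar, Cajal body, vault, 4.5S, RNase P and RNase MRP RNAs), a list chosen after seeing the data, were lower in Sdha-KO in 33 of 38 tested members, with a median log2 fold change of -1.69 with 6 libraries and -0.97 without both batch 1 libraries. With 6 libraries none passed over all genes in edgeR. Without both batch 1 libraries Rn4.5s passed (log2 fold change -1.55, adjusted p = 0.0266), and with the replicate block as well Rnu11, Rnu12, Snord89, Snora35, Snora81 and Vaultrc5 also did. Camera gave an unadjusted p of 2.62e-05 with the preset correlation and 0.108 with an estimated one. Because the list was chosen from these same data, neither value counts as evidence of a shift. Rnu11, a spliceosomal RNA, had 760 CPM in wildtype and 272 CPM in Sdha-KO libraries, Snord89 had 614 and 225 CPM, and the vault RNA Vaultrc5 had 327 and 98.9 CPM. The abundant small RNA row Rn4.5s took 8.40%, 0.944% and 1.16% of counts in wildtype replicates 1 to 3 and 3.65%, 0.448% and 0.336% in Sdha-KO replicates 1 to 3, so it was lower within each batch. These RNAs lack poly(A) tails as a rule, and their counts from a poly(A)-primed kit are not a measure of their abundance.

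Xist had 0, 4608 and 6055 counts in wildtype replicates 1 to 3 and 2683, 498 and 822 in Sdha-KO replicates 1 to 3, and the Y-linked gene Ddx3y had 222, 0 and 143 and then 0, 354 and 432. Wildtype replicate 3 and Sdha-KO replicates 2 and 3 held both.

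For the 5 genes and 14 lists past the threshold, of 10 splits of the 6 libraries into 3 and 3, 1 (the real one) gave as many as 5 genes, the highest of the others giving 0, and 1 gave as many as 14 lists, the highest of the others giving 12; 10 splits are too few for a share under 0.05. The split with 12 lists puts wildtype replicate 1 with Sdha-KO replicates 1 and 2 and so keeps the batch 1 libraries together, while the 3 other splits that part all 3 pairs gave at most 4 lists and 0 genes. Over 3 scalings the genes kept their direction, with a smallest absolute log2 fold change of 1.96 (Ear1 on library totals, where it was not called). The scalings moved the values by far less than the differences themselves, so this test could hardly have come out otherwise. For sex, batches 1 and 2 were compared. In batch 1 Xist was counted in Sdha-KO and Y-linked genes in wildtype only. In batch 2 Y-linked genes were counted in Sdha-KO only and Xist was lower there. A gene set by sex alone would differ in opposite directions in these batches. The 5 genes went the same way in both, with a smallest log2 ratio in the direction of the genotype difference of 2.01. Their groups did not overlap with 6 libraries, so this shared direction was fixed when the genes were chosen. No separate conclusion on sex is drawn from it. Loss of Sdha may be the cause of the differences in the 5 genes, as a hypothesis. Handling differences between genotypes within a batch and a part played by sex stay open. The Sdha-KO mice also carry Cre at the Lyz2 locus, whose effects this design cannot tell apart from loss of Sdha. A difference in the mix of sorted cells was not tested for these genes.

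The batch 1 libraries held few genes, although they had the most counts outside Rn45s (5247666 and 6700164, against 2463202 to 4443014 in the others). These totals argue against lower read depth as the cause. Thinned to 2408319 counts without Rn45s and Rn4.5s, the better batch 1 library had at most 68.7% of the genes of the lowest other library in 20 thinnings. Thinning took many counts from the batch 1 libraries, so it could hardly have closed the gap. Few molecules before amplification is a candidate explanation. Of genes with at least 100 counts in the other 4 libraries, Sdha-KO replicate 1 lacked 34.1% in the lowest of 3 equal classes of abundance and 3.66% in the highest, a ratio of 9.33. Other ways of losing transcripts can also spare abundant genes, so this ratio cannot single out few molecules. Both batch 1 libraries lacked 61 of these genes, against 39.5 from chance within these classes. No biological explanation was tested, and both genotypes show the pattern.

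The third pattern is the higher level of H2-Aa, H2-Ab1, H2-Eb1 and Cd74 in Sdha-KO. Each batch holds 1 library of each genotype, so a shift shared by a batch could not by itself produce it, whatever the ratios were. The smallest log2 ratio within a batch over the 4 genes was 1.47. For H2-Aa, H2-Eb1 and Cd74 the groups did not overlap, so the sign of these ratios was fixed in advance. Dendritic cells in the sort, which carry CD11c and MHC class II but should lack SiglecF and F4/80, cannot be told apart from a change in macrophages, with a median log2 fold change of 1.46 for their fixed list. The summed CPM of its 14 genes was 48.5, 61.7 and 79.8 in wildtype replicates 1 to 3 and 49.2, 160 and 405 in Sdha-KO replicates 1 to 3, or 11.2%, 8.47% and 6.50% and then 2.63%, 4.56% and 6.17% of the MHC class II sum. A first version of the test took these lower ratios as excluding dendritic cells; it was replaced after the values were seen, because with a background of the markers in wildtype libraries the ratio can fall even where such cells are added.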
